A study of Drosophila melanogaster with 3 samples.

How the data were processed

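Chromatin immunoprecipitation with sequencing was carried out on whole embryos of Drosophila melanogaster collected 0 to 24 hours after egg laying, with both sexes pooled. The flies carried a transgene for Atf3 fused to green fluorescent protein, and an antibody against the tag was used, per the labels. Chromatin was sheared to fragments of 200 to 800 bp, per the labels' protocols. The 3 biological replicates form 1 group. The labels name no treatment and no second group, so no comparison between groups was made.

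For each of the assemblies dm6 and dm3 there were 5 peak lists, 10 in all. Each replicate had a relaxed list made from its own alignment and a control file, per the labels. A further relaxed list was made from the 3 replicates pooled. The last list holds the peaks kept at a threshold on the irreproducible discovery rate (IDR), a measure of how repeatably a peak ranks across replicates. The relaxed lists include background calls, per the labels. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The signal value of each peak was deposited by the authors and is their own value; it was used here only to describe, rank or filter peaks within a list. The second deposited value is the −log10 q of each peak, which reached its maximum in 82.0% of the dm6 IDR peaks and was therefore not used for ranking. Peak lists carry no read totals, so the depth of each sample is unknown, and all intervals given here cover counting error only.

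The 2896 dm6 IDR peaks were identical to the 2896 pooled calls with the highest signal. Membership thus followed pooled signal, and a single IDR peak need not rank alike in every replicate. Of the IDR peaks, 149 were not found in all 3 replicate lists. Sequence came from the release 6 genome, which is the dm6 assembly, and genes from Ensembl annotation release 115. Pseudogenes and transposable elements were left out, which left 17896 genes with 23722 transcription start sites (TSSs) on arms 2L, 2R, 3L, 3R, 4 and X. The dm3 lists were only counted, and no coordinates were converted. Each summit was assigned 1 class in the order promoter (within 500 bp of a TSS), 5' UTR, CDS, 3' UTR, non-coding exon, intron, intergenic. The class of non-coding exons was added to the order fixed beforehand.

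Peaks were called shared when the overlap covered at least 50% of the shorter interval. Chance levels came from 1000 rotations of the peaks along their own arms, with two-sided permutation p-values that cannot go below 0.002. Spearman correlations across peaks and differences of median log2 signal were tested with 100000 permutations, with a smallest p of 1e-05. The density on X was tested with a two-sided exact binomial test. For 12 motifs, matches on either strand in the 201 bp at the summit were compared with windows 600 bp to either side by a two-sided exact McNemar test against 1 flank drawn per peak. Ratios of motif shares have 95% bootstrap intervals from 2000 resamples. For 26 gene lists, protein-coding genes with an IDR summit within 500 bp of any TSS were called bound and tested against the other protein-coding genes with the two-sided Fisher exact test. Each family of tests was adjusted by the Benjamini-Hochberg method, and shares have 95% Wilson intervals. To give values per replicate, the 2896 peaks with the highest signal were taken from each replicate list and are called its top peaks. P-values over peaks or genes treat these as independent units, and do not measure the spread between embryos.

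The groups, tests, motifs, gene lists and alternative settings were fixed before the data were examined. Named genes were those nearest the 15 IDR peaks of highest signal, up to 4 members with the highest-signal promoter peak of each list with an adjusted p under 0.05, up to 2 of each other list, and Atf3, Jra, kay, crc and puc whether bound or not. For 6 list members a current gene symbol replaced the listed one, and the ban microRNA gene, which is not protein coding, was left out of its list. Alternatives covered the overlap rule, the number of top peaks, the promoter and motif windows, the control windows, the background genes, stricter peak sets and leaving out each replicate in turn. Leaving out a replicate kept the IDR peaks that overlapped the top peaks of both other replicates; the IDR list itself had been made from all 3.

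The steps were tested on simulated data. In the simulated motif test the planted motif was called and 0 of 10 unplanted motifs were. In the simulated list test the planted list was called in 93.5% of 200 rounds and unplanted lists in 0.1%. The planted list had a larger bound share than every list tested here except the cytoplasmic ribosomal proteins. How often lists with the smaller shares seen here would be called was not simulated. In the simulated test of medians, a shift of 0.3 SD was called in 90.0% of 100 rounds and no shift in 6.0%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.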

Results

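Atf3 is a basic leucine zipper (bZIP) transcription factor of the ATF/CREB family. Its binding was profiled in whole fly embryos through a fluorescent tag, in 3 biological replicates of 1 group. The dm6 lists held 2896 IDR peaks, 27754 pooled calls and 30000 calls for each replicate. In the IDR list 84.2% of the intervals were 400 bp wide.

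The 15 IDR peaks of highest signal ranked 23 or better in each replicate list. The first lay 110 bp from the TSS of CG14100 (FBgn0036889), at 3L, start 19590433, end 19590799, with a signal of 1627 and a mean rank of 1.67 ± 1.15 (SD, n = 3) in the replicate lists. The second was in an intron 1402 bp from the nearest TSS, that of cbt (FBgn0043364), a zinc finger transcription factor, at 2L, start 480882, end 481294, with a mean rank of 1.67 ± 0.58 (SD, n = 3). The next peaks were nearest to px, a gene of wing vein patterning, to Ugalt, a nucleotide sugar transporter, and to ph-p, a Polycomb group gene. Their signals were 1558, 1470 and 1280. The others in the set were nearest to Chro, a chromatin protein of the mitotic spindle, Art3, an arginine methyltransferase, CG11050, CG1888, CG13323, PNPase, a mitochondrial ribonuclease, Lk6, a protein kinase, CenG1A and CHMP2B, a membrane-sorting protein. Of the 15 peaks, 10 lay at promoters and 0 held a CRE/ATF motif. That motif was in 1.52% of all IDR peaks, so a count of 0 among 15 is not informative.

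The Atf3 promoter itself held the peak of rank 6 (FBgn0028550). This peak spanned X, start 1275287, end 1275703, in intergenic sequence 202 bp from the TSS, with a signal of 1255 and a mean replicate rank of 6.67 ± 1.53 (SD, n = 3). Further IDR peaks lay in an Atf3 intron and upstream, with signals from 92.8 to 364. Jra and kay, the fly Jun and Fos genes, were also bound at their promoters, with signals of 134 and 129. Their replicate ranks varied widely, at 9345 ± 10217 for Jra and 3481 ± 2631 for kay (SD, n = 3). The promoter of crc, the fly ATF4 gene, had a pooled call but no IDR peak. The promoter of puc, a phosphatase that limits JNK signalling, likewise had no IDR peak, although 7 IDR peaks lay within 1 kb of the gene body.

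**Figure D1:**
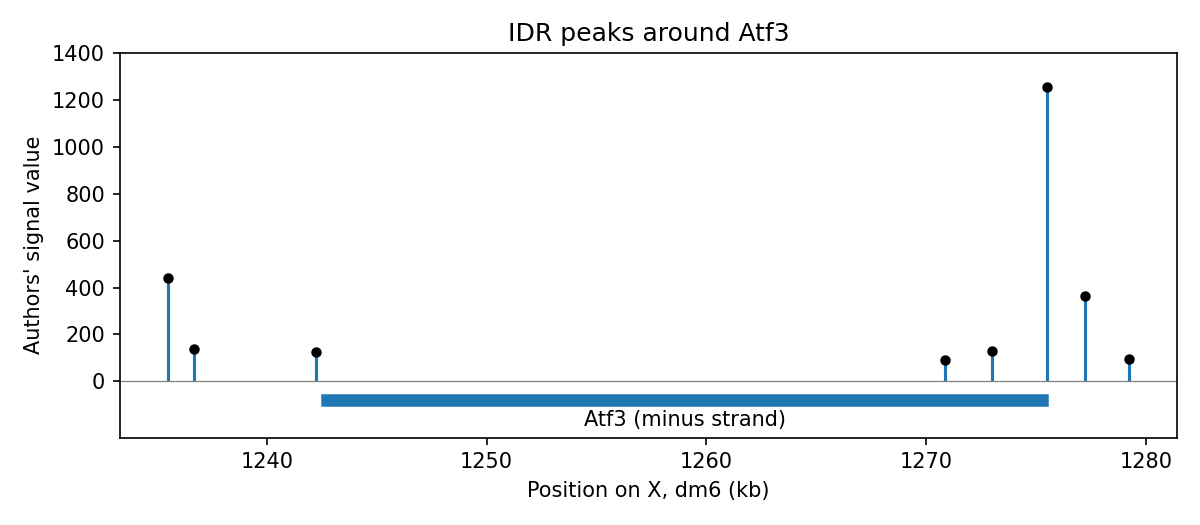
IDR peaks around Atf3 on X in dm6, with position in kb on the x axis and the authors' signal value on the y axis. Each line is a summit and the bar is the gene, and the highest peak, with a signal of 1255, stands 202 bp from the TSS.

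Agreement of the replicates was measured first over the IDR peaks. In the replicate lists 98.2% ± 1.08 (SD, n = 3) of IDR peaks were found, and 94.9% (Wilson interval 94.0% to 95.6%) were found in all 3. Rotated peaks were found in all 3 lists in 1.51% of cases (permutation p = 0.002, the smallest the rotations can give). The IDR list was derived from these same lists, so the overlap is not independent evidence. Among the top 2896 peaks of each replicate, replicates 1 and 2 shared 61.7%, replicates 1 and 3 shared 63.6%, and replicates 2 and 3 shared 68.5%, against 0.828% to 0.865% by chance. Spearman's rho of signal across IDR peaks, which are not independent replicates, was 0.489, 0.558 and 0.703 for the same pairs (permutation test, adjusted p = 1e-05 for each of the 3, the smallest it can give).

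**Figure D2:**
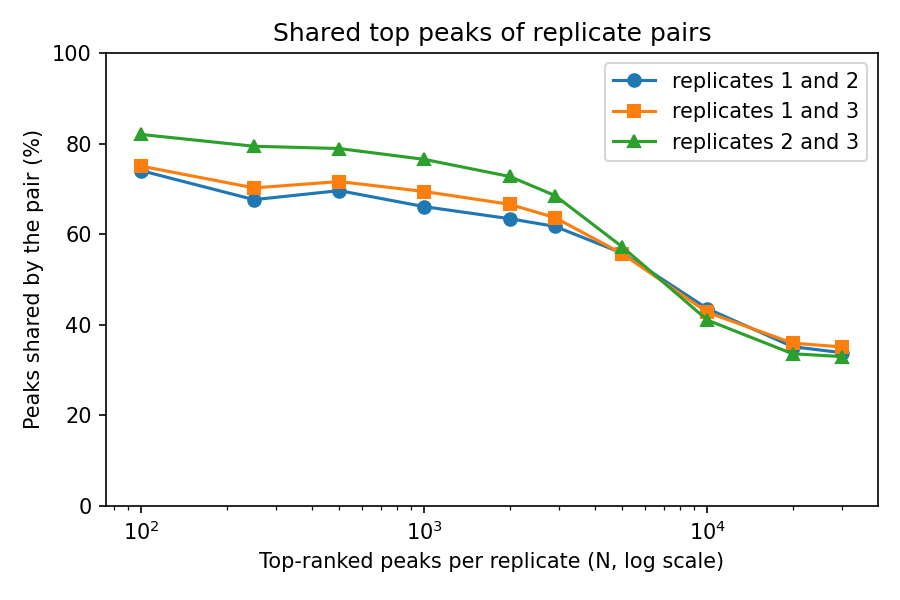
Share of top-ranked peaks shared by each pair of replicates (y axis, percent) against the number of top peaks taken from each (x axis, log scale). Replicates 2 and 3 shared 82% of their top 100 peaks, and the other pairs 74% and 75%.

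Promoters held more IDR peaks than rotated peaks. At 53.8% (Wilson interval 51.9% to 55.6%), 1557 summits lay within 500 bp of a TSS, against 13.5% of rotated peaks (permutation test, adjusted p = 0.0028). Over the top peaks of each replicate the promoter share was 52.6% ± 3.17 (SD, n = 3), and it was lowest in replicate 3, at 49.0%. The share of IDR peaks was 43.2% with a window of 250 bp and 63.4% with 1000 bp. Among the 24858 pooled calls outside the IDR set it was 23.8%. It fell with signal, from 53.8% in the first 2896 pooled calls to 43.9% in the next 2896, 31.2% in the third such set and 17.2% in the last 1690. Introns held 32.1% of IDR peaks and intergenic sequence 12.1%, both below the rotated shares of 39.5% and 27.4% (permutation test, adjusted p = 0.0028 for each). Coding sequence outside promoters held 0.311% of IDR peaks, or 9 peaks, but 19.9% of the other pooled calls. Promoter peaks had a higher signal than distal peaks, with a difference of median log2 signal of 0.11 (bootstrap interval 0.05 to 0.17; permutation p = 0.00015, adjusted p = 0.0003).

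**Figure D3:**
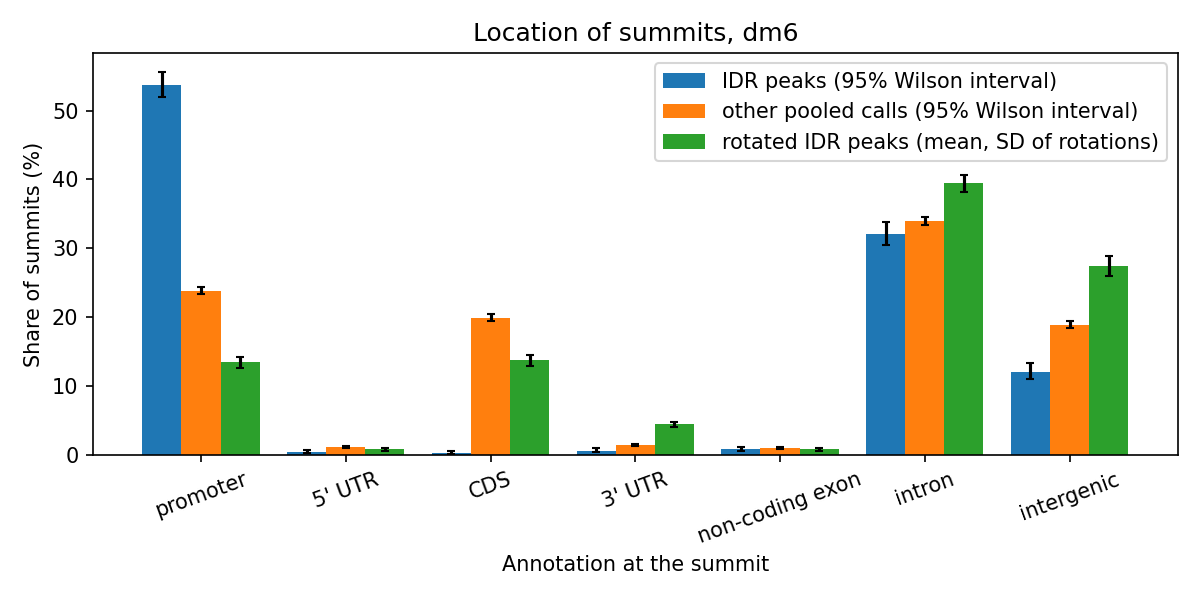
Share of summits (y axis, percent) by annotation class (x axis) for IDR peaks, other pooled calls and rotated IDR peaks. Bars on the first 2 are 95% Wilson intervals and on the rotated set the SD of rotations; promoters hold 53.8% of IDR peaks and 23.8% of other pooled calls.

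By chromosome arm, X held 517 IDR peaks and the large autosome arms 2367. Relative to gene number, X was denser than the autosome arms by a ratio of 1.20 (exact binomial p = 0.00022). The ratio over the top peaks of each replicate was 1.20 ± 0.09 (SD, n = 3). Relative to arm length, the ratio was 1.01 (exact binomial p = 0.81), so the excess on X was called only against gene number. Arm 4 held 12 IDR peaks.

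Motifs at the summits included the CRE/ATF palindrome TGACGTCA, the site bound by ATF/CREB proteins. It was present in 44 IDR peaks, or 1.52%, against 0.328% of flanking windows, a ratio of 4.63 (bootstrap interval 2.69 to 8.50; exact McNemar test, adjusted p = 3.6e-07). The replicates differed in this motif. It was in 2.35% of the top peaks of replicate 1 (ratio 5.67, adjusted p = 1.5e-11), 0.622% of those of replicate 2 (ratio 1.89, adjusted p = 0.54) and 0.967% of those of replicate 3 (ratio 2.95, adjusted p = 0.0077; exact McNemar tests chosen after the values were seen). In IDR peaks within the top peaks of all 3 replicates the CRE/ATF ratio was 3.00 and the call was lost (15 peaks, exact McNemar test, adjusted p = 0.31; 2.4e-05 to 0.31 over the alternatives). When only replicates 2 and 3 had to hold an IDR peak the ratio was 3.09 (17 peaks, exact McNemar test, adjusted p = 0.0029). With replicates 1 and 3 it was 4.36 (24 peaks, adjusted exact p = 0.0057), and with replicates 1 and 2 it was 3.00 (18 peaks, adjusted exact p = 0.017). The call was thus lost at a ratio that was called in another set of few peaks, so its loss alone does not show a weaker excess. CRE/ATF was called in promoter peaks (ratio 6.00, adjusted exact p = 0.01) and in distal peaks (ratio 3.64, adjusted exact p = 0.024). Only the distal split was among the alternatives. The motif of the AP-1 family, bound by Jun and Fos dimers, was not called, at 2.45% against 2.12% (exact McNemar test, adjusted p = 1), although in the later tests it was called in the top peaks of replicate 1 (ratio 1.40, adjusted p = 0.041). Peaks with and without CRE/ATF differed in median log2 signal by 0.02 (bootstrap interval −0.17 to 0.29; permutation p = 0.88), and without replicate 2 the difference was −0.000757.

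Core promoter motifs were also more frequent at summits than in the flanks. The DRE motif, bound by the promoter factor DREF, was in 4.39% of IDR peaks against 0.518% of flanks (ratio 8.47, adjusted exact p = 2.4e-25). The M1BP motif, another core promoter element, reached 1.97% against 0.380% (ratio 5.18, adjusted exact p = 1.6e-08), and the TATA box 29.6% against 19.7% (adjusted exact p = 1.5e-19). DRE was in 7.84% of promoter peaks and 0.373% of distal peaks, and the M1BP motif in 3.53% and 0.149%. The TATA box showed no such split, with 467 of 1557 promoter peaks and 390 of 1339 distal peaks. It was also called in distal peaks (ratio 1.30, adjusted exact p = 0.023). GC content was 37.8% in the summit windows and 43.4% in the flanks, so the TATA box excess over the flanks was not separated from base composition. The M1BP ratio was 3.18, 3.06 and 2.59 without replicates 1, 2 and 3. Against pooled calls outside the IDR set, matched on promoter class and GC content, none of these 3 motifs was called: the ratios were 1.17 for DRE, 1.06 for M1BP and 0.944 for the TATA box (Fisher exact test, adjusted p = 0.43, 0.85 and 0.31). Over all alternatives the adjusted exact p ran from 7.5e-31 to 1 for DRE, 9.8e-18 to 0.85 for M1BP and 1.3e-18 to 0.31 for the TATA box. CRE/ATF was still called against the matched calls (ratio 2.93, adjusted exact p = 0.0011), and so were the GAGA factor motif (ratio 1.82, adjusted exact p = 0.00025) and TGACGT, the CRE core (ratio 1.37, adjusted exact p = 0.026). The matched calls came from the whole list outside the IDR set. The 2896 pooled calls ranked next after the IDR peaks held CRE/ATF in 42 cases (1.45%, Wilson interval 1.07% to 1.95%), close to the 1.52% of IDR peaks (1.13% to 2.03%), and the set after that in 1.10%. The GAGA motif and the TGACGT core were not called against the flanks in the main windows (ratios 1.13 and 1.29, adjusted exact p = 0.67 and 0.13). Both were called against the flanks in wider windows (GAGA ratio 1.42, TGACGT ratio 1.34, adjusted exact p = 1.6e-05 and 0.00048; both up to 1 over the alternatives). Both were also called in the top peaks of replicate 1 (GAGA ratio 1.68, TGACGT ratio 1.88, adjusted exact p = 3e-05 and 7.4e-09), in the tests chosen after the values were seen, and in those of neither other replicate. Without replicate 1 their ratios to the flanks were 0.789 and 0.893, and the GAGA ratio was 0.928 without replicate 2 and 0.981 without replicate 3. The C/EBP, composite, E-box and scrambled motifs were called against neither control, in any alternative. The motif of Zelda, an activator of the early embryonic genome, was not called in the main windows (ratio 0.659, adjusted exact p = 0.18). It was less frequent than in the flanks in narrower windows (ratio 0.356, adjusted exact p = 0.048; 0.048 to 0.92 over the alternatives). The same was seen in promoter peaks (ratio 0.308, adjusted exact p = 0.017), a split that was not among the alternatives. Against the matched calls the Zelda ratio was 1.23 (Fisher exact test, adjusted p = 0.68). The lower share than in the flanks was thus not separated from base composition.

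**Figure D4:**
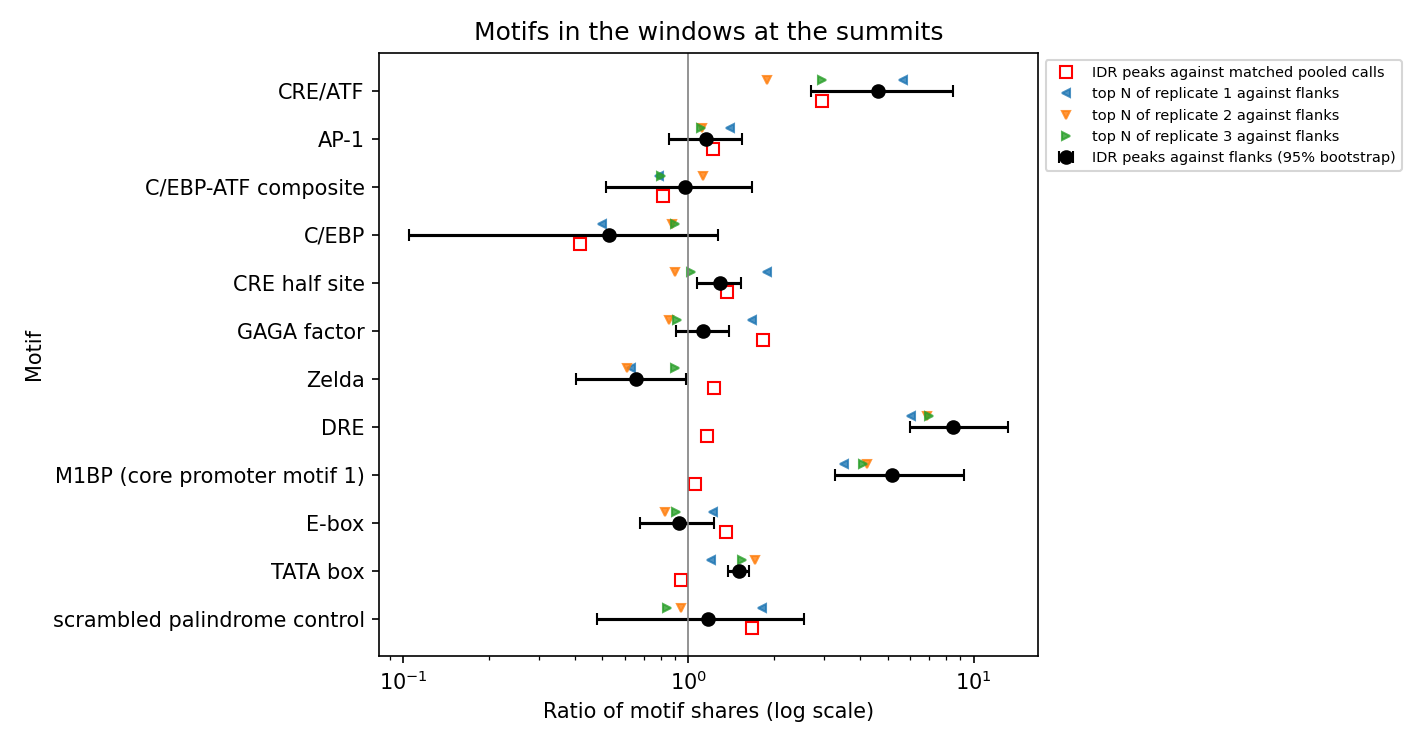
Ratio of motif shares (x axis, log scale) for each of the 12 motifs (y axis). Black points with 95% bootstrap intervals compare IDR peaks with flanks, open squares compare them with matched pooled calls, and triangles are the top peaks of each replicate; for CRE/ATF the triangles span 1.89 to 5.67.

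Cytoplasmic ribosomal protein genes were the most often bound of the 26 gene lists. Of 85 measured members, 57 (67.1%, Wilson interval 56.5% to 76.1%) had an IDR peak at the promoter, against 14.2% of all protein-coding genes (odds ratio 12.7, Fisher exact test, adjusted p = 2e-27). The share over the top peaks of each replicate was 60.8% ± 8.83 (SD, n = 3). The strongest were RpS27 (signal 550), RpL7 (438), RpL14 (358) and RpL34b (356). The median summit lay 48 bp from a TSS of the gene, and 0 of these peaks held CRE/ATF while 16 held DRE. Among all promoter IDR peaks CRE/ATF was in 1.54% and DRE in 7.84%, so 0 CRE/ATF matches among the ribosomal protein peaks is not informative. This was the only list called when the background was restricted to genes with a pooled call at the promoter (odds ratio 7.09, adjusted exact p = 2.1e-14; 4e-32 to 3.9e-14 over the alternatives). Without replicate 1, 37 of the genes were bound and the odds ratio was 6.97.

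Glycolytic genes were bound in 6 of 12 cases (odds ratio 6.08, Fisher exact test, adjusted p = 0.030), led by Gapdh2 (signal 300), Hex-A (245), Eno (206) and Pgk (186). The bZIP transcription factors were bound in 8 of 18 cases (odds ratio 4.87, adjusted exact p = 0.024). These included Atf3 itself (signal 1255), where binding and extra copies of the tagged locus cannot be told apart. The other named members were Irbp18 (signal 318), a C/EBP-like partner protein, CrebB (224), the fly CREB gene, and Xbp1 (138), a factor of the unfolded protein response. The CrebB peak ranked 108, 3858 and 755 in the lists of replicates 1, 2 and 3. The bZIP call was lost without replicate 1 (odds ratio 3.41, adjusted exact p = 0.19) and without replicate 3 (odds ratio 3.78, adjusted exact p = 0.18), and its adjusted exact p ran from 0.0095 to 0.76 over the alternatives. Those 2 sets were smaller, at 1910 and 1773 IDR peaks, so the losses do not by themselves show dependence on 1 replicate. The set without replicate 2 was also small, at 1815 IDR peaks, but kept the call (odds ratio 5.11, adjusted exact p = 0.032). It bound 6 of the genes, against 5 in each of the sets without replicate 1 or 3. Set size and dependence on a replicate were thus not told apart. The bZIP call was also lost in peaks held by all 3 replicates and within 250 bp (adjusted exact p = 0.10 and 0.059). The top peaks of replicates 1, 2 and 3 taken singly bound 8, 7 and 7 of the 18 bZIP genes. Glycolysis was called in all alternatives except the background of genes with a pooled call (adjusted exact p = 0.76; from 0.0066 over the others). Mitochondrial ribosomal protein genes were bound in 19 of 73 cases (odds ratio 2.14, adjusted exact p = 0.042). Their strongest members shared peaks with a neighbour: that at mRpS10 (signal 1164) was nearest to Art3 and that at mRpS23 (946) to CenG1A. When only the nearest TSS counted, 7 members were bound and the odds ratio was 0.966 (adjusted exact p = 1). The call was also lost without replicate 1, 2 or 3 (odds ratios 2.30, 1.62 and 1.75), and the adjusted exact p ran from 0.054 to 1 over the alternatives. The other 2 named members were mRpL41 (929) and mRpL23 (529). The top peaks of replicates 1, 2 and 3 taken singly bound 16, 21 and 19 of the 73 mitochondrial genes.

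The remaining 22 lists did not pass the test with the main settings. JNK signalling genes were bound in 6 of 17 cases (odds ratio 3.31, Fisher exact test, adjusted p = 0.13), among them Mkk4 (signal 642), a kinase upstream of JNK, and raw (240). Without replicate 1, 1 JNK gene was bound and the odds ratio was 0.552, and without replicate 3 the odds ratio was 0.612. With a promoter window of 1000 bp, 8 were bound (odds ratio 4.58, adjusted exact p = 0.019; 0.019 to 1 over the alternatives). With the same window, 8 genes of Hippo signalling, a growth control pathway, were bound (odds ratio 5.16, adjusted exact p = 0.016; 0.016 to 0.76 over the alternatives). Cell cycle genes were bound in 6 of 19 cases (adjusted exact p = 0.18), with dpa and RnrS the strongest. With the main window, Hippo signalling genes were bound in 5 of 16 cases (yki, Mer), Notch signalling genes in 5 of 18 (numb, E(spl)m7-HLH) and stress response genes of the unfolded protein pathway in 4 of 12 (Ire1, Xbp1). Vacuolar ATPase genes were bound in 8 of 33 cases (Vha55, Vha100-2), autophagy genes in 4 of 13 (Atg17, Atg18a) and proteasome genes in 4 of 32 (Rpn5, Rpn3). Heat shock genes were bound in 3 of 14 cases (Hsp83, Hsp26), lipid metabolism genes in 3 of 15 (Lpin, Lip4), epithelial polarity genes in 3 of 16 (par-6, dlg1) and ecdysone genes in 3 of 22 (Eip75B, usp). Germline markers (bgcn, piwi) and circadian clock genes (sgg, dco) were each bound in 3 of 10 cases, and segmentation genes in 3 of 21 (bcd, nanos). JAK/STAT genes were bound in 2 of 11 cases (Socs36E, Stat92E), oxidative stress genes in 2 of 14 (Keap1, cnc), Imd and Toll immunity genes in 2 of 26 (cact, imd) and muscle markers in 2 of 14 (sls, Mef2). Tracheal genes were bound in 2 of 12 cases (rtv, bnl), neuronal markers in 1 of 15 (elav) and Hox genes in 0 of 8 (Wilson upper bound 32.4%). Some of the named peaks ranked unevenly across replicates. The raw peak ranked 95, 2948 and 5817 in replicates 1, 2 and 3. Those at Stat92E and nanos were not found in the replicate 2 list, and that at Socs36E ranked 16647 there. The piwi peak ranked 13512 in replicate 1 and the Mef2 peak 11531 in replicate 3.

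**Figure D5:**
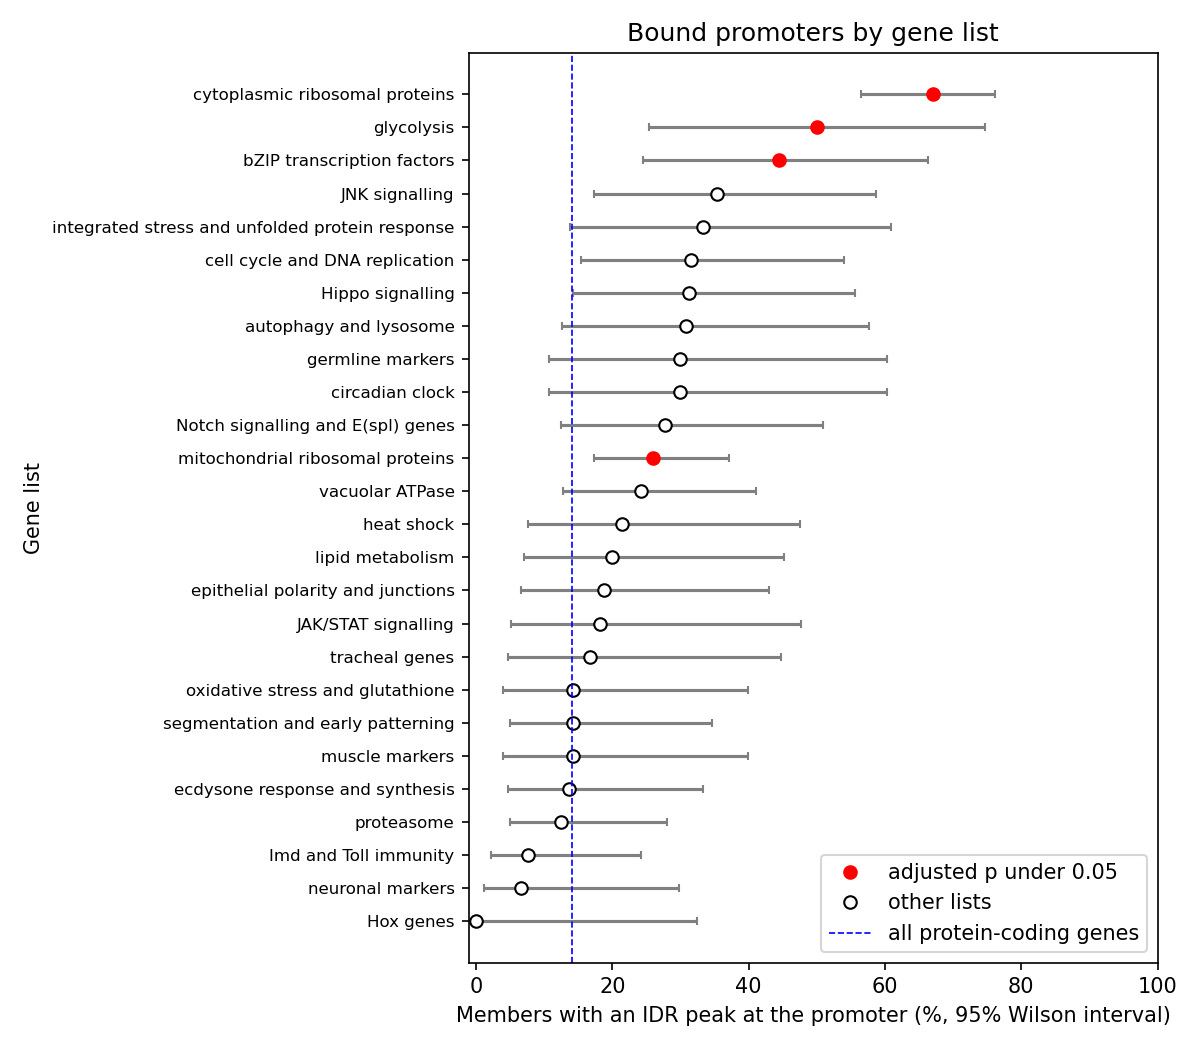
Share of the members of each gene list with an IDR peak at the promoter (x axis, percent, with 95% Wilson intervals) for the 26 lists (y axis). Filled points have an adjusted exact p under 0.05, and the dashed line is the 14.2% of all protein-coding genes; cytoplasmic ribosomal proteins stand highest at 67.1%.

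On the older assembly, dm3, the IDR list held 2615 peaks, 281 fewer than on dm6. The pooled list held 20235 calls on dm3 and 27754 on dm6.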

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

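Calls on sequence outside the 6 chromosome arms appeared in the relaxed dm3 lists, which enter no comparison here beyond counts. There were 50 such calls in the list of replicate 1, 484 in that of replicate 2, 422 in that of replicate 3 and 89 in the pooled list. Each is above the 3 calls that a count of 0 allows. Most lay on the unplaced heterochromatic parts of arms 2R, 3L and 3R, and the dm3 IDR list held 0. No explanation for these calls was tested.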

How the results depend on the processing

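All alternatives were set beforehand. Of the values under alternatives for results that answer a comparison, 47 were labelled unchanged, 18 moved, 1 lost its call and 3 reversed. Of those for single motifs and gene lists, 243 were unchanged, 7 gained a call, 20 lost one and 72 reversed. The cause was not tested for any of these. Unchanged meant the same direction and call, or for untested shares a move within the spread. Numbers of called motifs or lists were labelled unchanged when similar in size, whichever members were called. The 3 motifs called against matched calls were labelled so, although only CRE/ATF was among the 4 of the main windows. The share of IDR peaks in all 3 lists (94.9%) was 97.0% with an overlap of 1 bp, 78.5% with 80%, 84.6% with summits within 100 bp, 98.3% for the 1448 peaks of highest signal and 95.4% to 97.4% without a replicate. The shared top peaks (64.6%) were 56.8% with an overlap of 80%, 59.3% by summits, 69.3% with the top number at 1448, 52.8% at 5792 and 61.7% to 68.5% without a replicate. The promoter share ran from 43.2% within 250 bp to 63.4% within 1000 bp and stayed above the rotated share in all alternatives. The X ratio was 1.01 by arm length. Of 4 called motifs, 2 were called in peaks held by the top sets of all 3 replicates and 2 in distal peaks. Of 4 called lists, 2 were called in peaks held by all 3, 2 within 250 bp, 1 with the pooled-call background and 2 to 3 without a replicate. The signal difference by CRE/ATF was −0.17 in the stricter set, −0.0461 with the TGACGT core and −0.000757 to 0.11 without a replicate.

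Motif ratios reversed as follows. In distal peaks they were 1.43 for the composite, 0.912 for GAGA, 1.27 for Zelda, 0.833 for DRE, 0.444 for M1BP and 0.833 for the scrambled control. In narrower windows they were 1.14 for C/EBP, 0.857 for GAGA and 0.857 for the scrambled control, and in wider windows 1.15 for the composite and 1.10 for the E-box. Against matched calls they were 1.23 for Zelda, 1.36 for the E-box and 0.944 for the TATA box. In peaks held by all 3 replicates they were 0.986 for the TGACGT core and 0.865 for GAGA. Without a replicate they ran from 0.893 to 1.12 for the TGACGT core, 0.789 to 0.981 for GAGA and 0.884 to 1.08 for the E-box.

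Odds ratios of lists reversed as follows. In the stricter set they were 0 for JAK/STAT, oxidative stress and tracheal genes, 0.824 for lipid metabolism, 1.15 for ecdysone, 1.19 for proteasome, 0.577 for segmentation and 0.888 for muscle. In peaks held by all 3 replicates they were 0.714 for JNK, 0 for JAK/STAT and tracheal genes, 0.879 for oxidative stress and muscle, 0.816 for lipid metabolism, 1.14 for ecdysone and 0.571 for segmentation. Within 250 bp they were 0.789 for JAK/STAT, 0.526 for polarity, 0.607 for oxidative stress and muscle, 1.25 for ecdysone, 1.13 for proteasome, 0.394 for segmentation and 0.986 for Notch, and within 1000 bp 0.857 for oxidative stress, segmentation and muscle. With the pooled-call background they were 0.922 for JAK/STAT, 0.864 for polarity, 0.576 for oxidative stress and 0.768 for muscle. By nearest TSS they were 1.44 for ecdysone, 0.966 for mitochondrial ribosomal proteins and 0.958 for segmentation. Without a replicate they ran from 0.552 to 1.36 for JNK, 0 to 1.02 for JAK/STAT, 0.68 to 1.70 for oxidative stress, 0.631 to 1.57 for lipid metabolism, 0.884 to 1.02 for ecdysone, 0.589 to 1.01 for proteasome, 0.442 to 1.07 for segmentation, 0.68 to 1.63 for muscle and 0 to 0.891 for tracheal genes. Peak lists give no depth, so its effect on these values is unknown.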

Other observations

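Tests of highly transcribed genes, of peaks held by 1 replicate and of 8-base words were chosen after the results they concern were seen. The matched calls and the peaks without replicate 1 were alternatives set beforehand, but were taken as tests of explanations for the CRE/ATF excess only after it was seen. Peaks in the top set of 1 replicate alone differed in sequence. Of 788 such peaks in replicate 1, 42 (5.33%, Wilson interval 3.97% to 7.13%) held CRE/ATF, against 1 of 656 in replicate 2 and 3 of 596 in replicate 3 (odds ratio 17.6, Fisher exact test, adjusted p = 3.6e-13). The GAGA factor motif was in 12.1% of them against 2.59% and 4.36% (odds ratio 3.85, adjusted exact p = 6.2e-13). DRE was in 3.55%, 4.12% and 1.51% (adjusted exact p = 0.58). The TATA box was less frequent in the peaks of replicate 1, at 134 of 788 against 231 of 656 and 161 of 596 (odds ratio 0.450, adjusted exact p = 8e-13). The sets also differed in GC content, at 44.0%, 37.2% and 41.4% for replicates 1, 2 and 3, and in promoter share, at 54.2%, 50.6% and 32.0%, so the GAGA and TATA box differences were not separated from base composition. For CRE/ATF, the scrambled palindrome of the same composition was in 4 of the 788 peaks of replicate 1 (0.508%, Wilson interval 0.198% to 1.30%), below the CRE/ATF interval. The palindrome leaned the same way between replicates, with 1 of 656 in replicate 2 and 0 of 596 in replicate 3 (odds ratio 6.38, Fisher exact test, p = 0.077, adjusted p = 0.18), so a part of the CRE/ATF difference from base composition was not excluded. The libraries are single samples of the same group, so this describes replicate 1 and no condition.

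Among 28991 words of 8 bases, 5 were more frequent at IDR summits than at matched pooled calls and 1 was less frequent. CACTGTGC was in 5.04% of IDR windows against 2.07% (ratio 2.43, Fisher exact test, adjusted p = 2.8e-05), and CACAGTGG in 4.66% against 2.00% (ratio 2.33, adjusted p = 0.00025). Neither contains the TGACGT core. The CRE/ATF word TGACGTCA, in 44 IDR windows against 15, did not pass among this many words (ratio 2.93, Fisher exact test, adjusted p = 0.16). Of the CRE/ATF sites within 500 bp of a TSS, 24 of 298 (8.05%, Wilson interval 5.47% to 11.7%) lay within 100 bp of an IDR summit. For DRE sites this was 135 of 1558 (8.66%, 7.37% to 10.2%) and for the scrambled palindrome 5 of 223 (2.24%, 0.961% to 5.14%). Of the distal sites, 21 of 1596 for CRE/ATF, 6 of 2461 for DRE and 5 of 1535 for the scrambled palindrome lay as near. The strongest IDR peaks with the motif were nearest to l(2)gd1 (signal 581), Fur1 (462) and Vha55 (357), named after their values were seen.

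The position of IDR peaks at promoters was set against technical explanations. The IDR share was 29.9 percentage points above that of the other pooled calls. The IDR peaks are the pooled calls of highest signal, and a promoter bias of calling or shearing would raise that signal too, so the bias set as an explanation beforehand and binding at promoters cannot be told apart by this gap. Recovery of highly transcribed genes whatever their function also remains open. For this, 27 housekeeping genes outside the ribosomal protein list were chosen from background knowledge and not from expression measured here. Of these, 13 were bound (48.1%, Wilson interval 30.7% to 66.0%), among them Act5C, Hsc70-4, Rack1 and eEF2. This interval overlaps that of the ribosomal protein genes (Fisher exact p = 0.11). Part of the ribosomal protein result may therefore reflect transcription level, and binding by Atf3 was not separated from it. For the glycolytic genes, bound in 6 of 12 cases, the Wilson interval of 25.4% to 74.6% held the housekeeping share of 48.1%. They were not tested against the housekeeping genes, so the glycolysis result was not separated from transcription level either.

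The CRE/ATF excess was weighed in the same way. A scrambled palindrome of the same composition had a centre to flank ratio of 1.18, with a bootstrap interval up to 2.55, below the CRE/ATF interval that starts at 2.69. Against matched pooled calls from the whole list the CRE/ATF ratio was 2.93, which argues against the choice of flanks as the whole source. The motif was not particular to IDR peaks, since the 2896 pooled calls ranked next held it in 1.45% of cases against 1.52%. Without replicate 1 the ratio was 3.09 (17 peaks, exact McNemar test, adjusted p = 0.0029), and replicate 3 alone gave a call, which argues against replicate 1 as the whole source. The IDR list itself drew on all 3 replicates, and replicate 2 alone gave no call. Of the IDR peaks, 1.52% held the site, and binding of the tagged protein to it was not tested.

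Calls around Atf3 could come from extra copies of the tagged locus. The 40 kb around the gene held 14 pooled calls (Poisson interval 7.65 to 23.5), against a 95th percentile of 15 and a 99th of 19 for windows on X. The window held 5 IDR peaks, against a 95th percentile of 3 and a 99th of 5, a number that 2.04% of windows reached. By the rule set beforehand, a pooled count no higher than the 95th percentile spoke against extra copies, and 14 against 15 met it. The Poisson interval was added after the count was seen and spans both bounds. With that interval, extra copies and binding at the locus cannot be told apart here. In replicate 1 the same window held 25 calls, a number that 1.06% of windows on X reached. In replicates 2 and 3 it held 12 and 9 calls, numbers that 13.7% and 33.9% of windows reached. The pooled count was reached by 8.80% of windows. With 1 group, no biological explanation was tested for this or the preceding patterns.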
